A study of Mus musculus with 2 samples.

How the data were processed

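RNA was sequenced from 2 libraries of cells sorted from breast tumours of FVB mice, 1 of tumour-initiating cells (TIC) and 1 of non-tumorigenic cells (NTC). Per the labels' protocols, total RNA was extracted with a column kit, amplified to cDNA with a kit for small inputs, fragmented and made into sequencing libraries. Amplification from little RNA can change the share of reads a gene gets with its length and base composition, and reads copied by PCR are not independent molecules. The groups are those the sample descriptions give. How many tumours or animals each library came from, and the surface markers of the sort, are not given in the sources used here.

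The values used are FPKM per gene as deposited by the authors, which divide a gene's fragments by its length and by the library's mapped fragments. The submitters' processing notes name CASAVA 1.8.2, TopHat 1.4.0, Cufflinks, Cuffdiff and the mouse genome build mm9, without their roles or settings. The heading of the locus column names a human build, but the loci are those of mouse genes. Of 20009 symbols also found in the NCBI gene table of build GRCm38, 99.7% lay on the same chromosome, and 4.42% of starts lay within 1 kb of those in GRCm38, so the positions are not of that build. Positions are given in mm9 as in the processing notes, counted from 1. The starts in the files equalled the GRCm38 start for 12 genes and were 1 below it for 198, so 1 was added to each. No symbol occurred more than once among 22558. For 1568 genes the files give a description of several gene identifiers in place of a name, so their values may combine or split transcripts of neighbouring or related genes. Genes of this kind named in the text are Rpl41, Plb1, Idh2, Pdk3, Pgd, Hmgcs1, Phgdh, Dsp, Ly6a, Lamc1, Nrg1, Nrg2 and Fgg. Genes with near-identical copies or processed pseudogenes, such as Eno1, Eef1a1 and the ribosomal protein, Ly6 and haemoglobin genes, are uncertain, because the sources do not say how shared reads were assigned.

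FPKM are not counts, and no count model was fitted. Depth was estimated from low values of olfactory and vomeronasal receptor genes with a locus below 1.5 kb. A value multiplied by the locus length in kb clustered near what 1 read is worth, which was taken as the median of the values between 0.035 and 0.065, 0.0476 in TIC (23 genes) and 0.0463 in NTC (39 genes). That window limits the estimates, so they give the depth only roughly. Of values up to 3 reads, 30 of 46 in TIC and 49 of 60 in NTC lay within 0.15 of a whole number of reads. The FPKM of all genes summed to 332935 in TIC and 376464 in NTC, and the 100 highest genes held 22.8% and 27.5% of these sums. The estimates cover counting only, and not the variation between animals or sorts, which 1 library per group cannot show.

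Ratios were log2((TIC + 1)/(NTC + 1)), with a pseudocount of 1 FPKM, among the 12004 genes with a mean of at least 1 FPKM, which are called measured. Genes with a log2 ratio of at least 1 in either direction were counted as at least 2-fold different. Before the data were examined, 53 gene lists with 1040 entries were written, of which 1019 entries were found in the files. The lists cover energy and biosynthetic metabolism, mitochondria, mammary lineages, signalling, cell cycle, stress and other cell types, and the 5 lists of respiratory complexes were also joined. For each list with at least 3 measured members, the median log2 ratio was given its percentile among 10000 random lists of the same size, drawn from measured genes in 20 bins of mean expression. A list below percentile 2.5 or above the matching upper bound is described as lying outside the central 95%. The percentile describes these libraries and is not a test of the conditions. Of 47 lists scored, 16 were low and 10 high, against 2.35 that chance would place outside if lists were random draws. The lists share members and their genes vary together, so this chance number is only a guide. The 7 others had fewer than 3 measured members and are described by their values. They are those of T and NK cells, B cells, neutrophils and mast cells, endothelial cells, erythroid cells and skeletal muscle, and the genes of the mitochondrial genome, which were not analysed here.

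The genes named were fixed by rule before the data were examined. They are the 12 genes with the largest ratio in each direction among those with a mean of at least 5 FPKM, leaving out predicted genes, clone names, small RNAs and antigen receptor segments. In each list they are up to 4 members with the largest ratio in the direction of the median and up to 2 in the other direction. Each measured gene of pyruvate dehydrogenase, its regulators and the sorting antigens was also named, with the 5 highest genes of each library and the highest marker of each other cell type. Some genes that this rule takes are not reported here. Ndufs5, Ptprc, Snai1, Twist1, Twist2, Zeb1, Zeb2, Foxc2 and, in the closing section, further genes were named after their values were seen.

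The procedure was tested on simulated data made from the real genes' means (12012 measured genes) for the TIC and NTC comparison. All 99 genes changed by 3 on the log2 scale were counted as at least 2-fold different, as were 90.8% of 98 genes changed by 1.5 and 2 of 11739 unchanged genes. A simulated list of 76 genes with a small shift lay below all random lists, and 6 of 100 random lists of 20 genes lay outside the central 95%. The simulated noise was of 1 fixed size at every expression level and independent between genes, without noise from read counting, amplification or shared regulation. These rates therefore check the calculation and do not give the error rates of the real libraries. Alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, centring on the median gene, rescaling to the same sum with and without the 100 most abundant genes, means in place of medians, and random lists that were unmatched or matched also on transcript length or GC content in 10 by 10 bins. Transcript length and GC content were medians over GENCODE vM21 transcripts and were found for 98.9% of measured genes. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.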

Results

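Gene expression was measured by RNA sequencing in cells sorted from breast tumours of FVB mice, an inbred laboratory strain. The cells were dissociated from the tumours and sorted by flow cytometry straight away, without treatment. The first library held tumour-initiating cells (TIC), the sorted fraction that gives rise to new tumours. The second held the non-tumorigenic cells (NTC). Each group had 1 library, so the data have no replicates and allow no test, SD or p-value. Every difference given here is between these 2 libraries and not between the 2 kinds of cell in general. Levels are in FPKM (fragments scaled to the length of the transcript and to the mapped fragments of the library), and pairs of levels are given as TIC against NTC. The ratio of TIC to NTC is on the log2(FPKM + 1) scale, which understates the difference for low genes.

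The depth of each library was estimated from low values. In short olfactory and vomeronasal receptor genes, low values lay on steps, and the step that fits 1 read was 0.0476 FPKM × kb in TIC and 0.0463 FPKM × kb in NTC. The step was sought within a set window, so it gives the depth only roughly. This corresponds to about 21.0 M fragments in TIC and 21.6 M in NTC. A level of 1 FPKM then rests on about 21.0 reads per kb of transcript in TIC and 21.6 in NTC. Of 22558 genes, 7345 were listed at 0 in TIC, 7397 in NTC and 6158 in both. Ndufs5, a subunit of mitochondrial complex I that every respiring cell uses, was listed at 0 in both libraries, so an exact 0 is not read as absence. Of 264 genes of oxidative phosphorylation, the cytosolic and mitochondrial ribosomes and the proteasome, it was the only 1 listed at 0 in both. Among the genes with the highest levels in TIC were Rpl41, Eef1a1, Lars2 and Acta2, and the 5 highest in NTC were Rpl41, Lcn2, Fth1, Trf and Eef1a1. Lcn2, an iron-binding secreted protein, had 614.9 FPKM in TIC against 4769 FPKM in NTC, and Trf, the iron carrier transferrin, had 47.3 against 3476 FPKM.

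TIC and NTC differed over a large part of the transcriptome, with the TIC library high in genes of the basal mammary layer and the NTC library high in genes of the luminal, milk-producing layer. Of 12004 genes with a mean of at least 1 FPKM, 1749 (14.6%) were at least 2-fold higher in TIC and 1658 (13.8%) were at least 2-fold lower. A difference of at least 16-fold was seen for 237 genes higher in TIC and 131 lower. The other 8597 genes lay within 2-fold. The median log2 ratio over the 12004 genes was -0.16, so gene groups are compared below with random groups of matched expression, which carry the same shift. With a pseudocount of 5 the counts were 1086 higher and 921 lower. Which direction held more genes depended on the setting, since with a pseudocount of 0.1 there were 1924 higher and 1964 lower, and 1108 were higher and 1175 lower among genes with a mean of at least 5 FPKM, and 1952 higher and 1356 lower when ratios were centred on the median gene.

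The 12 genes with the largest ratios toward TIC included 3 of the basal and myoepithelial list, Sparc, Acta2 and Col17a1. Sparc, a matrix protein, had 1714 FPKM in TIC against 2.71 FPKM in NTC (chromosome 11, 55208003 to 55233582, build mm9). Acta2, smooth muscle actin, had 2101 against 6.13 FPKM (chromosome 19, 34315581 to 34329826), and Myl9, a myosin light chain, had 560.2 against 1.54 FPKM. Wif1, a secreted inhibitor of Wnt signals, had 486.3 against 0.381 FPKM (chromosome 10, 120471060 to 120537698). Ngfr, the low-affinity nerve growth factor receptor, had 373.9 against 0.274 FPKM. The others among the 12 largest were Cytl1 (538.9 against 0.527 FPKM), Col17a1 (424.4 against 0.754), Serpinb11 (373.1 against 0.592), Vcan (434.7 against 1.17), Col14a1 (231.1 against 0.176), Serpinf1 (541.5 against 1.81) and Antxr1 (215.5 against 0.287).

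In the other direction, the genes with the largest ratios toward NTC included milk and luminal genes together with Wnt1. Hp, the haemoglobin-binding protein haptoglobin, had 0.453 FPKM in TIC against 1052 FPKM in NTC (chromosome 8, 112099028 to 112103072, build mm9). Wnt1, a secreted growth signal that causes mouse mammary tumours when overproduced, had 0.220 against 550.4 FPKM (chromosome 15, 98620288 to 98624261). Csn1s1, a casein of milk, had 2.85 against 1719 FPKM (chromosome 5, 88095249 to 88111599), and Btn1a1, a protein of the milk fat globule, had 0.194 against 200.3 FPKM. Elf5, a transcription factor of the secretory lineage, had 0.363 against 295.4 FPKM, and Ehf of the same family had 0.683 against 261.0 FPKM. The remaining genes of the 12 were Expi (4.204 against 3020 FPKM), Krt19 (2.56 against 1176), Cldn3 (0.181 against 274.8), Cel (1.88 against 667.7), Spp1 (1.04 against 464.1) and Plb1 (0.0696 against 159.5).

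**Figure D1:**
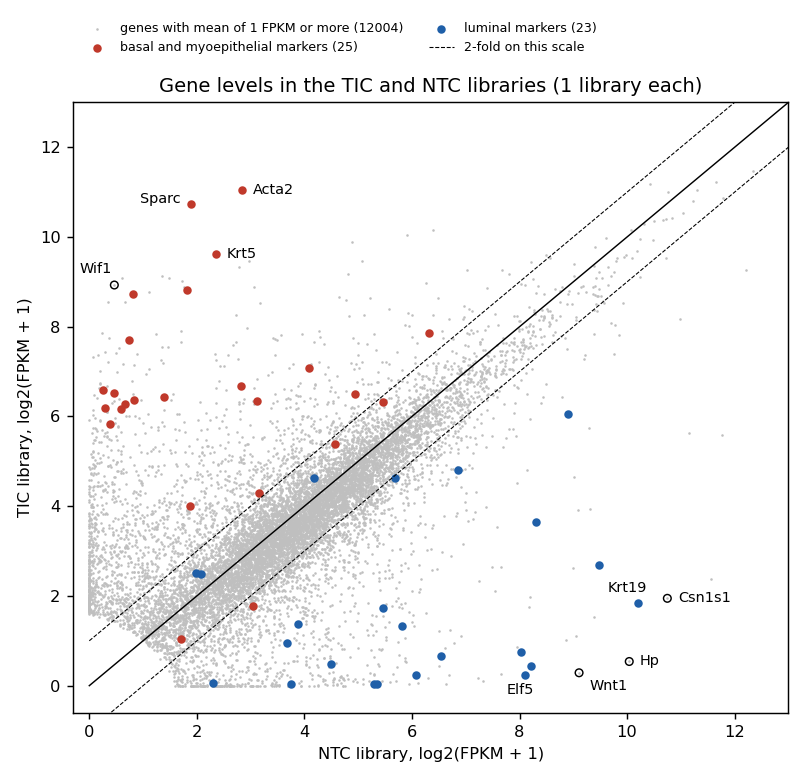
Each point is a gene with a mean of at least 1 FPKM (12004 genes), with its level in the NTC library on the x axis and in the TIC library on the y axis, both as log2(FPKM + 1). Dashed lines mark a 2-fold difference. Of 25 basal and myoepithelial markers (red), 21 lie above the upper dashed line, and of 23 luminal markers (blue), 20 lie below the lower one.

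Basal and myoepithelial markers were far higher in TIC, with 21 of 25 measured members at least 2-fold higher and 1 at least 2-fold lower. Their median log2 ratio of 5.43 lay above the medians of all 10000 random lists. Krt5, a keratin of the basal layer, had 782.8 FPKM in TIC against 4.13 FPKM in NTC, and Col17a1, a component of the junction to the basement membrane, had a log2 ratio of 7.92. Krt6a (2.44 against 7.26 FPKM) and Krt16 (1.04 against 2.26) were the members with lower values in TIC. Luminal markers were far lower in TIC, with 20 of 23 at least 2-fold lower and a median of -4.01, below all 10000 random lists. Besides Krt19, Elf5 and Ehf, this included Cldn3 of the tight junction, while Pgr (4.68 against 2.95 FPKM) and Prom1 (23.9 against 17.0) were slightly higher in TIC. Luminal progenitor and alveolar markers followed, with 14 of 18 at least 2-fold lower in TIC and a median of -4.34, again below all 10000 random lists. Csn2, another casein, had 5.20 against 511.6 FPKM, and Cd14 had 0.824 against 245.6 FPKM. The integrins Itgb3 (10.7 against 2.31 FPKM) and Itga2 (21.9 against 5.66) of this list were higher in TIC.

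Surface proteins that are used to sort mouse mammary cells differed in both directions. Of 13 measured, 7 were at least 2-fold higher in TIC and 5 at least 2-fold lower, and the median log2 ratio of 1.26 and the mean of -0.013 differed in sign. Thy1, a marker of basal mammary cells, had 3.06 FPKM in TIC and was listed at 0 in NTC, as was Procr, which had 3.42 FPKM in TIC. Cd44 had 132.7 against 29.4 FPKM, Itga6 230.0 against 78.4, Itgb1 159.1 against 65.8, Itgb3 10.7 against 2.31 and Itga2 21.9 against 5.66. Lower in TIC were Cd24a (268.7 against 829.4 FPKM), Epcam (153.8 against 589.0), Kit (89.2 against 282.6), Ly6a (23.9 against 50.5) and Cd14 (0.824 against 245.6). Prom1 had 23.9 against 17.0 FPKM. The gate used for the sort is not given in the sources used here. Differences in these genes may therefore be what the sort selected for, and so may differences in lineage markers that go with them.

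Genes of the cell junctions and of mesenchymal cells separated the libraries in the same way as the lineage markers. These lists share members, since Cldn3, Cldn4 and Cldn7 are also in the luminal list and Snai2 is also in the basal list. Among 21 epithelial junction genes, 12 were at least 2-fold lower in TIC, and the median of -1.17 lay below all 10000 random lists. The tight junction genes Cldn3, Cldn7 (0.590 against 92.0 FPKM), Cldn4 (0.181 against 66.3) and Tjp3 (0.0829 against 35.7) had the largest differences, whereas Dsp of the desmosome had 195.0 against 19.7 FPKM and Pkp1 28.6 against 14.1 FPKM. Of 11 measured mesenchymal transition genes, 10 were at least 2-fold higher in TIC, with a median of 2.85 that lay above all 10000 random lists, while the other 8 of the list of 19, among them the regulators Snai1, Twist1, Twist2, Zeb1, Zeb2 and Foxc2, were below 1 FPKM in both libraries. The transcription factor Snai2 had 90.9 against 0.382 FPKM, the protease Mmp2 54.3 against 0.290, N-cadherin (Cdh2) 30.8 against 0.170 and fibronectin (Fn1) 12.1 against 0.0849. The exception was Tgfb2, with 8.89 against 20.5 FPKM.

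**Figure D2:**
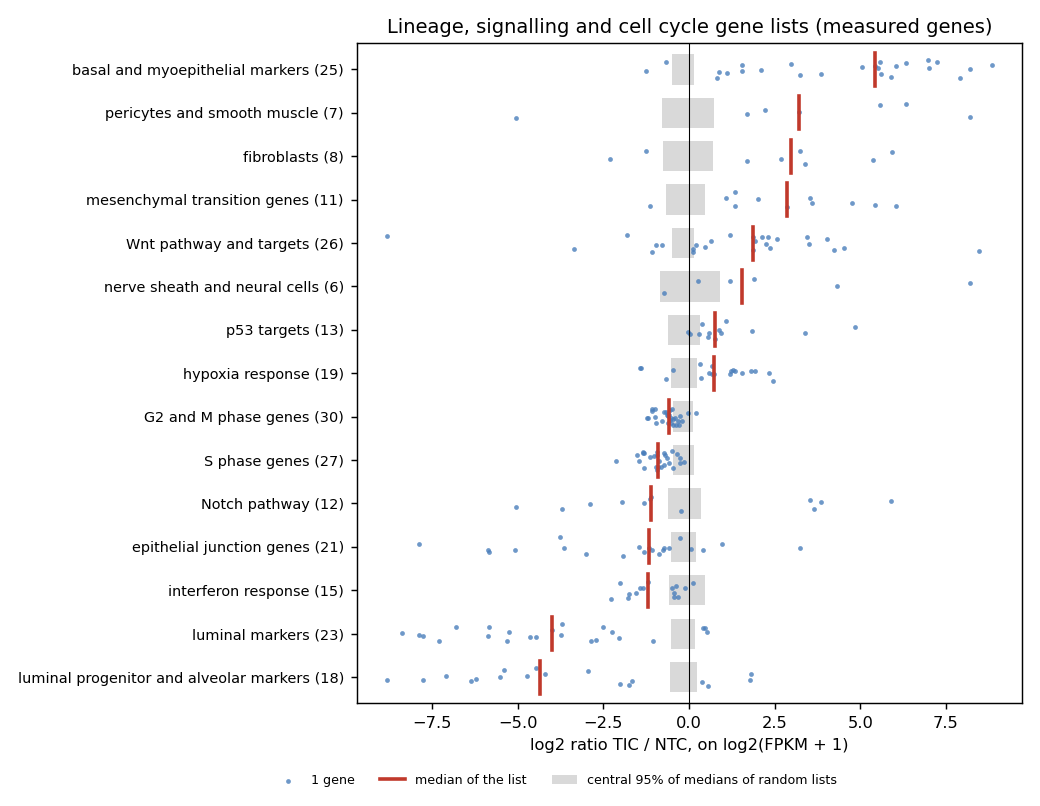
Each blue point is a measured gene of the list named at the left (number of genes in brackets), the red line is the list's median and the grey bar is the central 95% of medians of 10000 random lists matched on expression; the x axis is the log2 ratio of TIC to NTC. Medians run from 5.43 for basal and myoepithelial markers to -4.34 for luminal progenitor and alveolar markers.

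The title of the series names metabolism as its subject, so the genes of energy metabolism were compared next. Nuclear genes for the subunits of oxidative phosphorylation were lower in TIC as a group by a modest amount. Of 77 measured subunits of the 5 complexes, 76 had lower values in TIC, and 71 were lower by more than the median gene was. The difference reached 2-fold for 10, about the share among all measured genes (13.8%). The median log2 ratio was -0.56, and none of 10000 random lists had a median as low (their central 95% ran from -0.39 to -0.05). The largest differences were those of Ndufa4 (102.7 against 238.2 FPKM, chromosome 6, 11850373 to 11857446), Sdha (49.8 against 109.8 FPKM) and Ndufb7 (40.2 against 88.9 FPKM), apart from Cox7a1, which was listed at 0 in TIC and had 5.45 FPKM in NTC. Ndufa11 was the exception, with 27.5 against 20.2 FPKM.

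Taken by complex, the medians were -0.47 for the 36 genes of complex I, -0.73 for the 4 of complex II, -0.57 for the 9 of complex III, -0.86 for the 12 of complex IV and -0.55 for the 16 of ATP synthase. Complex IV, at percentile 0.47, and complex I, at percentile 1.26, lay below the central range of the random lists. Complex I was inside that range when the random lists were also matched on transcript length (percentile 6.92) or on GC content (2.78), and by its mean (3.38), and complex IV was inside it by its mean (percentile 6.37). Complexes II, III and ATP synthase were at percentiles 8.33, 9.12 and 4.79. Examples are Ndufb9 (80.9 against 167.9 FPKM) and Ndufb4 (5.06 against 11.4) of complex I, Sdhd (51.1 against 88.0), Sdhb (26.0 against 42.4) and Sdhc (75.9 against 87.3) of complex II, and Uqcrb (9.35 against 18.5) and Cyc1 (61.3 against 106.6) of complex III. Cox6b1 (93.2 against 196.3 FPKM) and Cox7c (58.7 against 119.9) of complex IV, and Atp5g1 (42.4 against 84.98) and Atp5g2 (68.3 against 134.5) of ATP synthase, had the same direction. Genes of the mitochondrial genome were not analysed here.

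The tricarboxylic acid (TCA) cycle, which feeds electrons into these complexes, was also lower in TIC, with 15 of 17 genes lower, 1 of them (Sdha) by at least 2-fold. The median log2 ratio was -0.69 (percentile 0.855), but the mean of -0.49 was at percentile 14.0, inside the central range. Idh3g had 65.8 FPKM in TIC against 130.8 FPKM in NTC, Suclg2 17.8 against 32.8 and Idh2 42.1 against 76.3. Idh3a (30.8 against 23.7 FPKM) and Sucla2 (17.4 against 15.1) were higher in TIC.

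Pyruvate dehydrogenase, the complex that passes pyruvate from glycolysis into the TCA cycle, had lower values in TIC for each of its 5 genes, all within 2-fold. Dld had 27.2 FPKM against 48.4 FPKM in NTC, Pdhb 23.7 against 37.4, Dlat 16.2 against 24.1, Pdha1 70.5 against 84.7 and Pdhx 7.84 against 9.58. The median of -0.54 was at percentile 12.4, so this small group did not stand apart from random lists. The kinases that switch the complex off differed in direction. Pdk2 was lower in TIC (29.3 against 87.7 FPKM, chromosome 11, 94887572 to 94902685), as was Pdk1 (9.10 against 14.9), whereas Pdk3 (8.98 against 3.26) and Pdk4 (5.55 against 0.812) were higher. Among the phosphatases that switch it on, Pdp1 had 2.51 against 1.43 FPKM and Pdp2 5.59 against 3.29, and the regulatory subunit Pdpr had 7.83 against 9.92. These 7 regulators had a median of 0.53 (percentile 94.6). The 8 genes of mitochondrial pyruvate and lactate handling had a median of -0.47 (percentile 13.2), with pyruvate carboxylase (Pcx) at 2.14 against 15.1 FPKM and Ldhb at 46.0 against 107.3, but the lactate transporters Slc16a7 (12.4 against 2.60) and Slc16a3 (12.05 against 3.87) higher in TIC. Brp44 and Brp44l, which form the mitochondrial pyruvate carrier, had 25.8 against 49.9 FPKM and 3.69 against 7.30 FPKM.

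Glycolytic genes did not share the lower values of the mitochondrial genes. Of 19 measured, 12 were higher in TIC and 7 lower, and 4 were at least 2-fold higher and 1 at least 2-fold lower. The median of 0.14 was at percentile 96.3, inside the central range, and at 98.4, outside it, when random lists were matched on transcript length as well. Eno1 (21.8 against 6.73 FPKM), Pfkp (17.6 against 6.63) and Pfkfb3 (19.5 against 9.07) were higher in TIC, and the glucose transporter Slc2a3 had 2.62 FPKM in TIC and was listed at 0 in NTC. Of these 4, Eno1 is uncertain because of near-identical copies. Slc2a3 rests on a 0, which is not read as absence. Aldoc was lower (60.2 against 291.0 FPKM), as was Pfkfb2 (5.50 against 10.2). Genes of the response to low oxygen, which overlap with glycolysis in function, were higher in TIC. Of 19, 9 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.74 (percentile 99.97). P4ha1 had 33.7 against 5.33 FPKM, Car12 110.8 against 21.0, Bnip3 21.2 against 4.78 and Egln3 85.2 against 23.8, while Ndrg1 (43.5 against 118.7) and Epas1 (3.95 against 11.99) were lower.

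**Figure D3:**
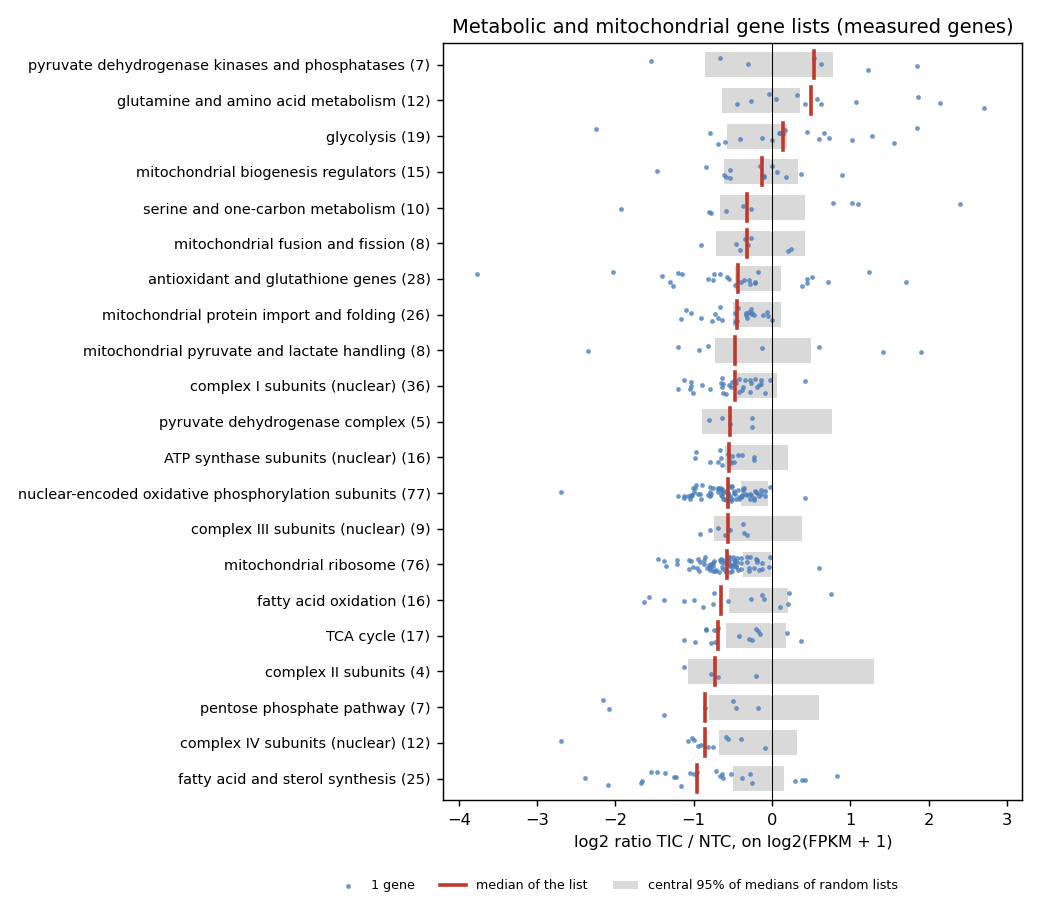
Each blue point is a measured gene of the metabolic or mitochondrial list named at the left (number of genes in brackets), the red line is the list's median and the grey bar is the central 95% of medians of 10000 random lists matched on expression; the x axis is the log2 ratio of TIC to NTC. The median of the 77 oxidative phosphorylation genes (-0.56) lies left of its grey bar, and that of the 19 glycolysis genes (0.14) lies inside it.

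Lower values in TIC extended to other anabolic and mitochondrial pathways. All 7 genes of the pentose phosphate pathway were lower, 3 of them by at least 2-fold (median -0.85, percentile 2.03), with Tkt at 27.4 against 125.6 FPKM, Taldo1 at 23.2 against 101.3, Pgd at 36.2 against 95.7 and G6pdx at 26.0 against 47.7. Of 25 genes of fatty acid and sterol synthesis, 11 were at least 2-fold lower and none at least 2-fold higher (median -0.96, below all 10000 random lists). The lipogenic regulator Srebf1 had 38.7 against 207.1 FPKM and the desaturase Scd1 51.5 against 223.0, and Pmvk had 4.73 against 17.3 and Idi1 3.74 against 14.0, while Hmgcs1 (25.9 against 14.1) and Srebf2 (54.0 against 40.0) were higher. In fatty acid oxidation, 4 of 16 genes were at least 2-fold lower (median -0.65, percentile 0.810), among them Acadm (10.01 against 33.3 FPKM), Eci1 (10.3 against 32.6) and Acaa2 (34.2 against 90.6), whereas Cpt1a, which controls entry of fatty acids into mitochondria, had 36.1 against 21.0. The mean of the list, -0.55, was at percentile 7.92, inside the central range. Amino acid metabolism went the other way, with 4 of 12 genes at least 2-fold higher in TIC and none at least 2-fold lower (median 0.50, percentile 98.7, and percentile 94.0 by the mean of 0.75). The amino acid exchanger Slc7a5 had 502.3 against 75.8 FPKM, its partner Slc3a2 303.5 against 82.5, the cystine carrier Slc7a11 6.38 against 0.670 and glutamine synthetase (Glul) 98.5 against 46.5. Gls2 (0.877 against 1.56 FPKM) and Got2 (71.0 against 85.9) were slightly lower.

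Of the genes that build and maintain mitochondria, those of the mitochondrial ribosome had the clearest difference. Lower values in TIC were found for 75 of 76, and 71 were lower by more than the median gene was. Their median was -0.57, below all 10000 random lists. At least 2-fold lower were 9, no larger a share than among all measured genes (13.8%). Cytosolic ribosomal protein and proteasome genes also had medians of -0.44 and -0.45. Mrps6 had 23.2 against 65.4 FPKM, Mrps18b 5.61 against 16.2 and Mrps22 4.40 against 12.7, and Mrpl20 was the exception with 36.6 against 23.8. The remaining groups lay inside the central range of random lists. They were the 26 genes of mitochondrial protein import and folding (median -0.44, percentile 5.91, with Tomm5 at 33.2 against 75.8 FPKM), the 8 of fusion and fission (median -0.33, percentile 29.1) and the 15 biogenesis regulators (median -0.13, percentile 54.9), whose median turned to 0.03 when ratios were centred on the median gene. Of these regulators, Ppargc1a had 7.09 against 3.36 FPKM and Ppargc1b 3.198 against 6.56. Antioxidant and glutathione genes were mixed, with 7 of 28 at least 2-fold lower and 2 at least 2-fold higher (median -0.43, percentile 4.92, and percentile 1.93 among genes with a mean of at least 5 FPKM). Gpx3 (1.95 against 39.3 FPKM), Gsr (6.86 against 31.1) and Cat (53.05 against 142.2) were lower in TIC, and Nfe2l2, the main regulator of this response, was higher (170.9 against 51.7). Serine and one-carbon genes had a median of -0.32 and a mean of 0.06 over 10 genes (percentile 28.1), with Phgdh at 11.5 against 1.37 FPKM and Shmt1 at 5.93 against 25.4.

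Wnt and Notch genes separated the libraries as well. Of 26 measured members of the Wnt pathway and its targets, 15 were at least 2-fold higher in TIC and 4 at least 2-fold lower, with a median of 1.88 above all 10000 random lists. Inhibitors and response genes led, with Wif1, Dkk3 (57.5 against 1.54 FPKM), the transcription factor Tcf7 (222.9 against 10.8) and the feedback inhibitor Nkd1 (21.6 against 0.383), whereas Wnt1 itself and Wisp2 (0.133 against 10.5) were lower in TIC. In the Notch pathway, 7 of 12 genes were at least 2-fold lower and 4 at least 2-fold higher. The median was -1.12 (percentile 0.040), but the mean was -0.036 (percentile 51.8), and with low genes kept the median was -0.23 (percentile 11.4). The receptors Notch3 (0.181 against 38.02 FPKM) and Notch1 (22.8 against 90.4) and the target Hey1 (2.54 against 44.9) were lower in TIC, and the ligand Jag2 (72.1 against 0.228) and the modifier Lfng (43.3 against 2.04) were higher. Regulators linked to stem cells went both ways, with 7 of 18 at least 2-fold higher in TIC and 5 at least 2-fold lower (median 0.14, percentile 92.5, and percentile 97.9 with low genes kept). Id4 had 146.7 against 0.275 FPKM and Aldh1a1 81.2 against 0.953, and Id2 had 7.26 against 81.1 and Nupr1 1.42 against 20.6.

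Genes of the cell cycle were lower in TIC. All 27 S phase genes had lower values, 9 of them by at least 2-fold, with a median of -0.91 below all 10000 random lists, and Mcm6 had 16.1 against 73.5 FPKM, Mcm5 12.2 against 36.4 and Cdt1 8.59 against 25.5. Of 30 G2 and M phase genes, 29 were lower, 28 of them by more than the median gene was (median -0.57, percentile 0.30). A 2-fold difference was reached by 4, about the share among all measured genes (13.8%). Ccnb2 had 18.99 against 45.6 FPKM and Birc5 14.1 against 33.7, with Nuf2 as the exception at 7.26 against 6.13. Targets of p53, a brake on the cell cycle, were higher in TIC for 12 of 13 genes, 4 of them by at least 2-fold (median 0.76, percentile 99.91). Phlda3 had 81.9 against 1.87 FPKM, Perp 395.0 against 36.5 and Sesn1 15.5 against 3.66, and Ei24 had 30.7 against 31.3. Whether p53 was more active, or whether its listed targets differ with basal against luminal lineage, was not tested. Cytosolic ribosomal protein genes were lower for 77 of 79, none by 2-fold (median -0.44, percentile 1.51), and with random lists matched also on transcript length, or by the mean, they were at percentiles 10.2 and 5.07. Proteasome subunits were lower for 29 of 31, none by 2-fold (median -0.45, percentile 3.04, and percentile 2.30 with random lists matched on GC content).

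Stress and immune response genes differed less evenly. Interferon response genes were lower in TIC for 14 of 15, with 8 at least 2-fold lower (median -1.20, percentile 0.030), among them Irf9 (6.51 against 24.2 FPKM), Gbp2 (0.817 against 6.38) and Ifih1 (0.0576 against 4.11). Class I antigen presentation genes had a median of 0.00 over 9 genes (percentile 76.0), with B2m at 772.2 against 360.4 FPKM and Tapbp at 21.4 against 45.4. Immediate early genes, which respond to tissue dissociation, had a median of -0.52 over 23 genes (percentile 3.50), with Fosb at 85.9 against 439.0 FPKM and Cyr61 at 85.05 against 344.4 but Egr3 at 40.4 against 4.37 and Egr2 at 49.6 against 5.70. This list was at percentile 0.830 among genes with a mean of at least 5 FPKM and at 1.95 against unmatched random lists. The 13 heat shock genes had a median of -0.32 (percentile 34.1), with Hspa4l at 0.821 against 9.68 FPKM and Bag3 at 107.3 against 30.4. The 19 genes of the unfolded protein response had a median of 0.00 and a mean of -0.15 (percentile 88.5), with Xbp1, which is high in secretory cells, at 65.4 against 478.2 FPKM.

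Many markers of other cell types in the tumour had values below 1 FPKM in both libraries. A large part of these values were exact 0s, which are not read as absence, in TIC for 7 of 12 general immune, 9 of 20 macrophage and dendritic cell, 12 of 17 T and NK cell, 7 of 9 B cell and 12 of 13 neutrophil and mast cell markers, and in NTC for 4, 6, 13, 8 and 9 of them. Among 12 general immune markers, Ptprc, the gene of CD45, was listed at 0 in both, and 8 members were below 1 FPKM in both. The 4 measured members had a median of 0.85 (percentile 93.0), with Arhgdib at 64.8 against 4.67 FPKM and Lcp1 at 21.6 against 81.5. Macrophage and dendritic cell markers were below 1 FPKM in both libraries for 15 of 20, and the 3 measured had a median of 0.57 (percentile 68.5), with the highest value, 2.52 FPKM in TIC, for Cd74. T and NK cell markers were below 1 FPKM in both for 16 of 17, apart from Cd247 (5.15 against 5.31 FPKM), and all 9 B cell markers were below 1 FPKM. Of 13 neutrophil and mast cell markers, 12 were below 1 FPKM in both, and S100a8 was listed at 0 in TIC and had 5.11 FPKM in NTC. Of 9 erythroid markers, 8 were below 1 FPKM in both, and Hba-a1 had 0.106 against 5.55 FPKM. All 12 skeletal muscle markers were below 1 FPKM, and 9 of 12 adipocyte markers were, with a median of -0.94 (percentile 6.05) over the 3 measured, Cebpa (18.6 against 8.82 FPKM), Lipe (5.85 against 12.1) and Lpl (0.0122 against 10.6). Among endothelial markers 13 of 18 were below 1 FPKM in both, but Eng had 70.7 against 13.3 FPKM.

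The exceptions were the lists of fibroblasts, of pericytes and smooth muscle, and of nerve sheath and neural cells, in which several members were high in TIC. Of 8 measured fibroblast markers, 6 were at least 2-fold higher in TIC and 2 at least 2-fold lower (median 2.98, above all 10000 random lists). Dcn had 151.8 against 1.51 FPKM, Fbn1 43.7 against 0.0803 and Col1a2 9.56 against 0.0119, whereas Col6a3 (1.18 against 9.79) and Postn (3.98 against 10.8) were lower, and 12 of the 20 members were below 1 FPKM in both. Of 7 measured pericyte and smooth muscle markers, 6 were at least 2-fold higher (median 3.202, above all 10000 random lists), led by Acta2, Myh11 (95.7 against 0.200 FPKM) and Cnn1 (71.3 against 0.501), which are also in the basal list, and Notch3 was lower. Of 6 measured nerve sheath and neural markers, 4 were at least 2-fold higher (median 1.55, percentile 99.50). They included Ngfr, Tubb3, which had 19.1 FPKM in TIC and was listed at 0 in NTC, and Ncam1 (12.3 against 2.59), while Sox10 was high in both libraries (345.8 against 288.1).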

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

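Each group has 1 library, so the alternatives show how the comparison of these libraries depends on the processing and not whether another pair of libraries would give it. Random lists matched on GC content were chosen after seeing the data. The counts of genes at least 2-fold different stayed within 1.5 times the reported counts, except with a pseudocount of 5 (1086 higher and 921 lower in TIC), which shrinks the ratios of low genes, and with a filter at 5 FPKM (1108 higher), which tests fewer genes. More genes were lower than higher with that filter (1175 lower) and with a pseudocount of 0.1 (1924 higher and 1964 lower). Centring subtracts 1 number from every gene, so it cannot move a percentile and is not counted here. Of 46 lists run under the 9 other alternatives, 33 kept their side of the central range in each, as did the macrophage list under the 8 that left it enough members. Pseudocounts of 0.1 and 5 moved none across its bounds, nor did rescaling without the 100 most abundant genes, which is 1 factor per library and can move percentiles little. By the mean in place of the median, complex I (-0.51), complex IV (-0.90), the TCA cycle (-0.49), fatty acid oxidation (-0.55), glutamine and amino acid metabolism (0.75), the Notch pathway (-0.036) and cytosolic ribosomal proteins (-0.43) no longer stood apart, and the sorting antigens turned from a median of 1.26 to a mean of -0.013. The mean gives weight to single genes with large ratios, such as Cd14 at -7.08 among the sorting antigens. With random lists matched on transcript length, complex I (-0.47) and cytosolic ribosomal proteins (-0.44) no longer stood apart and glycolysis (0.14) did. With lists matched on GC content, complex I (-0.47) no longer stood apart and proteasome subunits (-0.45) did. A filter at 5 FPKM brought antioxidant genes (-0.51) and immediate early genes (-0.62) outside the central range, and unmatched random lists did so for the immediate early genes (-0.52). Without a filter the Notch pathway (-0.23) no longer stood apart and stem cell regulators (0.17) did. Unless stated, the cause was not tested. Of 270 named genes, 65 moved by more than 1.5 times with a pseudocount of 0.1 and 84 with a pseudocount of 5. The sign of a 2-fold difference could not change in these runs. A pseudocount keeps the sign of a ratio, and centring and rescaling shift every gene by far less than 2-fold. A count of genes outside the authors' confidence intervals was not run, because no intervals were used here, and no symbol was repeated, so the choice between repeated symbols changed nothing. No paired analysis was possible because each group has 1 library. Depth limits the low genes, since 1 FPKM in a transcript of 1 kb rests on about 21.0 reads in TIC.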

Other observations

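The groups of genes in these opening paragraphs were put together after their values were seen. Genes that build the basement membrane were higher in TIC, with 15 of 19 measured at least 2-fold higher and none at least 2-fold lower (median log2 ratio 2.85). The type IV collagens Col4a1 (709.9 FPKM in TIC against 6.85 FPKM in NTC) and Col4a2 (638.9 against 5.86), the laminins Lama1 (163.5 against 5.003) and Lamc1 (229.1 against 38.1), Col18a1 (181.9 against 0.473) and Col7a1 (61.5 against 0.0696) were among them, while Lamb2 (10.8 against 21.6) and Lama4 (6.70 against 11.2) had lower values. Of 9 measured genes of ErbB growth factor ligands and receptors, 3 were at least 2-fold higher in TIC, 4 at least 2-fold lower and 2 within 2-fold. Nrg1 (102.1 against 0.254 FPKM), Nrg2 (15.0 against 0.0322) and Tgfa (39.3 against 3.57) were higher in TIC, and Areg (0.397 against 21.5) and Btc (0.0169 against 2.19) were higher in NTC. The neuregulin receptor gene Erbb3 (7.97 against 43.1) was also higher in NTC, and the receptor gene Egfr had 40.9 against 22.7. Of 9 D cyclins and inhibitors of cyclin-dependent kinases, 4 were at least 2-fold higher in TIC, 3 at least 2-fold lower and 2 within 2-fold. Ccnd2 was higher in TIC (98.2 against 0.133 FPKM) and Ccnd1 in NTC (326.8 against 691.5). Of 11 imprinted genes, 6 were at least 2-fold higher in TIC, 1 at least 2-fold lower and 4 within 2-fold. Mest (469.1 against 2.39), H19 (37.3 against 0.446) and Cdkn1c (79.3 against 3.18) were higher in TIC, and Peg3 (23.2 against 64.7) was lower.

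The NTC library was high in secreted acute phase and defence genes, with 14 of 14 measured at least 2-fold lower in TIC (median -3.86). Besides Hp and Lcn2 these included Clu (2.38 against 288.2 FPKM), Cp (1.14 against 119.5), Lrg1 (0.780 against 97.0), Ltf (0.194 against 49.3), C3 (1.57 against 37.2) and Fgg (0.765 against 40.9). Of 8 proton pump and acid secretion genes, 5 were at least 2-fold lower in TIC and 3 within 2-fold. The transcription factor Foxi1 was listed at 0 in TIC and had 39.6 FPKM in NTC, the proton pump subunit Atp6v1b1 had 0.170 against 102.2 FPKM and carbonic anhydrase Car2 had 0.767 against 42.3. The subunits Atp6v1a (27.8 against 49.1) and Atp6v1e1 (35.2 against 46.6), which most cells use, differed by less than 2-fold.

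The genes with the largest ratios also set a bound on how much RNA of the other kind each library held. For the 12 genes with the largest ratios toward NTC, the level in TIC was between 0.0400% (Wnt1) and 0.281% (Cel) of that in NTC. For the 12 with the largest ratios toward TIC, the level in NTC was between 0.0733% (Ngfr) and 0.334% (Serpinf1) of that in TIC. RNA of the other library's kind then made up no more than about 0.0400% of TIC and 0.0733% of NTC, provided that stray cells had that library's mean levels of Wnt1 and Ngfr. Stray cells without Wnt1 or Ngfr are not bounded in this way. Both values are the smallest of 12 and rest on few reads, and the medians of the 12 were 0.131% in TIC and 0.158% in NTC. These genes were chosen for their ratios, and other abundant genes were present in both libraries, such as Lcn2 (614.9 against 4769 FPKM) and Mfge8 (261.1 against 872.6).

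In the 3 patterns weighed next, the test of transcript length was set before its result was seen, and the tests of GC content, scaling, housekeeping genes, lineage, fibroblasts, pericytes, neighbouring genes, other Wnt genes and an added copy were chosen only after the data were seen.

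The first pattern is the lower level of oxidative phosphorylation genes in TIC. Short transcripts and base composition were not the whole cause, since the list stayed at percentile 0.080 with random lists matched on transcript length and at 0.010 with lists matched on GC content. A different scaling of the libraries moves every gene alike and was not the whole cause either, since the list lay below the median of all measured genes by -0.40 (interval over resampled genes -0.48 to -0.33). How far the shift is particular to respiration stays open, because 110 ribosomal protein and proteasome genes had a median of -0.44 as well and the list lay below them by only -0.12 (interval -0.21 to -0.05). Also open is whether the difference goes with tumour-initiating capacity or with basal against luminal lineage, which cannot be told apart with 1 library of each since basal markers differed by a median of 5.43 between them, and lower S phase genes in TIC leave slower growth as a further untested possibility.

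The second pattern is the high level of some fibroblast and smooth muscle genes in TIC. Fibroblasts in the sort would bring their most abundant transcripts together, and Col1a2 (9.56 FPKM), Col5a1 (8.77) and Pdgfra (8.83) were higher in TIC. However, Col1a1 had 0.459 FPKM, Col3a1 0.221 and Lum 0.573, and the higher of these 2 collagens was 0.303% of the level of Dcn. Dcn thus did not come with these 2 collagens, but they were chosen after their values were seen. Since other fibroblast genes were higher in TIC, fibroblasts in the sort are not excluded. Pericytes or vascular smooth muscle stay open, since Des (0.0303 FPKM) and Notch3 (0.181) were low in TIC, but Rgs5, Higd1b, Kcnj8 and Abcc9 were listed at 0, which is not read as absence. Of the 6 pericyte and smooth muscle markers at least 2-fold higher in TIC, Acta2, Myh11 and Cnn1 are also in the basal list, while Mcam (30.7 against 5.86), Cspg4 (8.51 against 0.0332) and Pdgfrb (2.44 against 0.0701) are not. That basal tumour cells themselves express Dcn, Fbn1 and the contractile genes is a hypothesis that these pooled values may fit but cannot show.

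The third pattern is Wnt1, at 0.220 FPKM in TIC and 550.4 FPKM in NTC. Transcription of the whole neighbourhood would carry nearby genes along, but of 6 measured genes within 100 kb the lowest log2 ratio was -0.41 (Fkbp11). No other Wnt gene was listed near this level, the highest in NTC being Wnt5b at 55.2 FPKM. Reads of a related gene that were counted for Wnt1 would be missing from that gene's level, so this cannot exclude them. Of 6 other Wnt genes measured, 3 were at least 2-fold higher and 3 at least 2-fold lower in TIC. An added copy of Wnt1 that is active in luminal cells is a candidate explanation, but reads of an added and of the native copy count for the same gene, so the level of 550.4 FPKM cannot tell these apart, and the labels used here name no tumour model. Wnt response genes were not uniform, with Tcf7, Nkd1 and Nkd2 (218.3 against 18.4 FPKM) higher in TIC, Axin2 (17.0 against 11.9) and Rnf43 (31.2 against 26.8) within 2-fold, and Ccnd1 (326.8 against 691.5), Myc (133.0 against 231.4) and Sox9 (51.2 against 100.6) at lower values in TIC.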
